A study of Mus musculus with 27 samples.

How the data were processed

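Spleen RNA of female NOD mice, a strain that develops autoimmune diabetes, was measured on 27 whole mouse genome arrays at 6 ages. There were 5 arrays at 10 days, 5 at 4 weeks, 3 at 8 weeks, 5 at 12 weeks, 4 at 16 weeks and 5 at 20 weeks. Each array held 2 dyes. Per the labels, the green dye (Cy3) carried the NOD sample and the red dye (Cy5) carried NOD.B10, a congenic control strain with another H2 haplotype, the mouse major histocompatibility complex. The dyes were never exchanged, so a dye bias of a probe cannot be separated from a strain difference. Per the labels' protocols, RNA came from a Qiagen RNeasy extraction and was labelled with an Agilent linear amplification kit. Every sample carries a diabetic label in the deposited characteristics, the 10-day mice included, and this label was not used.

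The deposited scanner files held spot intensities in both dyes. Per the submitters' processing notes the images were read with Agilent Feature Extraction 8.5, and per the file headers with version 8.5.1.1 on 19 arrays, 8.1.1.1 on 6 and 9.1.3.1 on 2. Per the file headers, the processed signal intensity of each dye was corrected for background with a spatial surface and normalised between the dyes by a linear and a LOWESS step, within each array only. Signals not above background had been replaced by surrogate values, per the file headers. The deposited value table held, per the labels, log10 of the NOD over the NOD.B10 processed signal. Its values equalled the negative of the log10 ratio column of the scanner files with a largest difference of 5e-05. The deposited 0 or 1 quality marks (other unit) gave saturation, outlier spots and whether a signal was well above background.

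From these the log2 ratio of green over red processed signal was computed for each spot, spots marked as outliers were set to missing, and the spots of a probe were averaged. A probe was kept where it was well above background in the green or the red dye on every array of at least 1 age, which left 35817 of 41174 probes. The brightest probe stood for each gene, giving 25990 genes, of which 17485 had a symbol. Symbols came from the RefSeq table of assembly GRCm38.p6. It matched 22072 probes by their accession, 135 by another accession of the probe and 7438 by their symbol, and 11529 probes had no match. No genome build is named in the files, so the table served only for names and for the order of neighbouring genes. Single-dye values were log2 signals relative to the 75th percentile of that dye on the array.

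The tests used limma 3.58.1 in R 4.3.3, with jsonlite 2.0.0 for reading. A single model with 1 mean per age and a shared spread was fitted to all 27 arrays. NOD was compared with the reference over the mean of the 6 ages and at each age, successive ages were compared, 20 weeks was compared with 4 weeks, and an F test covered any change from 4 to 20 weeks. The comparison of 20 weeks with 10 days was added after the scan days had been seen, because it can be made within 1 scan day. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and for NOD against the reference also with a log2 ratio of at least 1 in size. All p-values count both directions, except those of the control-spot permutations, which are 1-sided. The limma p-values measure the spread between arrays. Camera sets the genes of a list against other genes, and Fisher's exact tests count genes as units. Reference profiles of an age were close to identical on arrays of 1 scan day (r = 0.98 to 1 across genes) and less so between scan days (0.85 to 0.99), and whether the control mice were replicated is not recorded. The number of arrays limits the precision.

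Before the data were examined, 37 gene lists for cell types, other tissues and pathways and a list of sex-linked transcripts for checking labels were fixed, with the comparisons, the tests and most alternatives. Lists were tested against the other genes with camera at a preset correlation between genes of 0.01 and with an estimated correlation. They were also tested with fry, which asks whether the genes of a list move 1 way on balance and compares them with no other genes. Each test was adjusted over the 37 lists of a comparison. Counts of list members adjusted over the list alone use the adjusted p under 0.05 and no minimum fold. The text describes lists whose camera adjusted p was under 0.05 and whose median log2 value was at least 0.5 in size, a limit chosen after the values were seen. The share of H2 region genes among those that differed was tested with Fisher's exact test.

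Genes were named by a rule set before the data were examined: among genes that passed and had a symbol other than an accession, clone, Riken or predicted-gene name, the 10 highest and 10 lowest over all ages, the 3 highest and 3 lowest at each age, the 10 highest and 10 lowest of the longer age comparisons and the 5 highest and 5 lowest of the successive ones, the last 2 kinds only where the ages did not overlap array by array. The 10 genes with the widest range of age means, H2 region genes that passed over all ages, and list members with the lowest p were also named. Where a dye was not well above background on any array of a group, the fold is given as a bound computed at the background limit, or not at all. BC023719 was added after its values were seen.

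Scan days and scanners in the file headers gave 7 scan days, grouped after the files were seen into 5 scan campaigns on 3 scanners. Campaign 1 held the 4-week arrays and 1 array of 10 days. Campaign 2 held 2 arrays of 12 weeks and 1 of 8 weeks, campaign 3 the 16-week arrays and the other 12-week arrays, campaign 4 the 20-week arrays with 3 of 10 days and 1 of 8 weeks, and campaign 5 the last arrays of 10 days and 8 weeks. Alternatives covered the background correction (normexp with an offset of 50, then loess), the deposited ratios, the filter, the probe summary, array weights, the replicate number, the scan day or campaign as a block, arrays of 1 scan day or campaign only, the NOD dye alone, a stricter adjusted p of 0.01, and leaving out each array.

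The procedure was tested on simulated data with the ages, arrays and spread of each gene of the real data. Each gene was drawn independently, and 200 of 25236 genes were changed. For 20 weeks versus 4 weeks the test recovered 20.9% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 95.5% of those changed 4-fold, with 3.2% of its calls false. For 16 weeks versus 12 weeks it recovered 23.9%, 59.7% and 97% at the same folds, with 6.25% false. False calls at 8 weeks against the reference were 9.33%, by adjusted p alone and without the minimum log2 ratio that the report's calls use. In the NOD dye alone within scan day 6, for 20 weeks versus 10 days, it recovered 1.49%, 2.99% and 68.2% with 7.69% false, so most genes changed 2-fold or less were missed there (200 of 25846 changed), and the reference dye was not simulated. A shift of 0.6 given to 1 list was recovered in 13 of 13 simulated comparisons, and 2 of 468 unchanged lists were called. As the simulated genes were independent, this does not tell how often lists of correlated genes are called. Nothing was left out of the deposited arrays.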

Results

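The 27 arrays compared spleen RNA of NOD mice with spleen RNA of the NOD.B10 control strain, as ratios, at 10 days (n = 5), 4 weeks (n = 5), 8 weeks (n = 3), 12 weeks (n = 5), 16 weeks (n = 4) and 20 weeks (n = 5). The median spot signal per array was 109.2 to 262.1 in the NOD dye and 91.3 to 228.5 in the reference dye. Between 65% and 94.2% of spots were well above background in the NOD dye (median 80.8%) and between 51.8% and 83.1% in the reference dye (median 62.7%). Xist, the transcript that silences an X chromosome in females, was well above background in the NOD dye on 27 of 27 arrays. The Y-linked genes Kdm5d, Eif2s3y and Uty were so on 14, 21 and 19 of 27 arrays in the NOD dye and on 9, 4 and 2 in the reference dye. Their mean NOD levels were -3.54, -3.32 and -3.34 relative to the 75th percentile, against -0.13 for Xist. Red-dye profiles of the same age and scan day correlated at r = 0.98 to 1 across genes over 33 pairs of arrays. Those of different ages on the same scan day correlated at 0.89 to 0.98 over 36 pairs. Those of the same age on different scan days correlated at 0.85 to 0.99 over 16 pairs. On a shared scan day each age thus had a reference of its own, although the design text names control mice of 10 days and 20 weeks only. A difference between ages in the ratio can lie in either strain.

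The question over all ages was which genes differed between NOD and its congenic control whatever the age. The largest difference was that of D17H6S56E-5, a transcript encoded in the H2 region, at log2 -3.70 ± 0.08 (SE, 27 arrays), which is 13-fold lower in NOD and lower on 27 of 27 arrays (adjusted p = 3.6e-20). Sik1, a salt-inducible kinase, was 4.14-fold higher (log2 2.05 ± 0.09, adjusted p = 6.9e-14, higher on 26 of 27 arrays). C4b, a complement component encoded in the H2 region, was 2.73-fold higher (log2 1.45 ± 0.07, adjusted p = 7.8e-13, 27 of 27). The axonemal dynein Dnah8 was at log2 1.33 ± 0.05, but its 3 probes lay between -0.44 and 1.33. The eosinophil chemokine Ccl24 was at 1.18 ± 0.17, with age means of 2.34 at 12 weeks, 0.22 at 8 weeks and -0.49 at 20 weeks. Nlrx1, a mitochondrial protein of the NLR family, was at 1.41 ± 0.26, with 5.71 at 4 weeks, 6.88 on a single 10-day array and age means of 0.26 to 0.54 from 8 to 20 weeks. H2-T3, a non-classical class I gene, Tsga8, Csrnp3, Iqcj and Fam81b were also higher, but their reference dye was well above background on only 6, 9, 9, 4 and 2 of 27 arrays, so the size of these ratios was not measured. BC023719, a chromosome 17 transcript left out by the naming rule for its accession-like name, had the highest estimate of all genes (log2 2.21, adjusted p = 1.1e-12), with the reference dye well above background on 5 of 27 arrays. With the mean of probes Dnah8 (0.28), Nlrx1 (0.46) and Csrnp3 (0.73) did not pass. Among H2 region genes that passed, H2-Aa, the alpha chain of a class II molecule, stood at log2 1 ± 0.07, although the mean of its probes was -0.26. H2-T23, a non-classical class I gene, stood at -1.08 ± 0.07.

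In all, 184 of 25990 genes differed over all ages with limma, 51 higher and 133 lower in NOD, and 182 did with scan campaign as a block, 170 of them shared. With normexp background correction and loess 27 did (25 shared), and 28 when only genes well above background in both dyes on all arrays were kept. The adjusted p alone passed for 16237 genes, most of them with small ratios. Of 81 tested genes of the H2 region list, 4 differed (4.94%) against 180 of 25909 other genes (0.69%), an odds ratio of 7.42 (95% interval 1.95 to 20.1, Fisher's exact p = 0.0026). D17H6S56E-5 and BC023719 are not in that list and count among the other genes. Chromosome 17, which carries the H2 region, held 17 of the genes that differed among 848 tested, 2% against 0.505% elsewhere (odds ratio 4.03, Fisher's exact test, adjusted p over 20 chromosomes = 0.00013). Of these, 16 lay between Tbc1d24 and H2-T3 in gene order, a stretch picked after the values were seen.

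**Figure D1:**
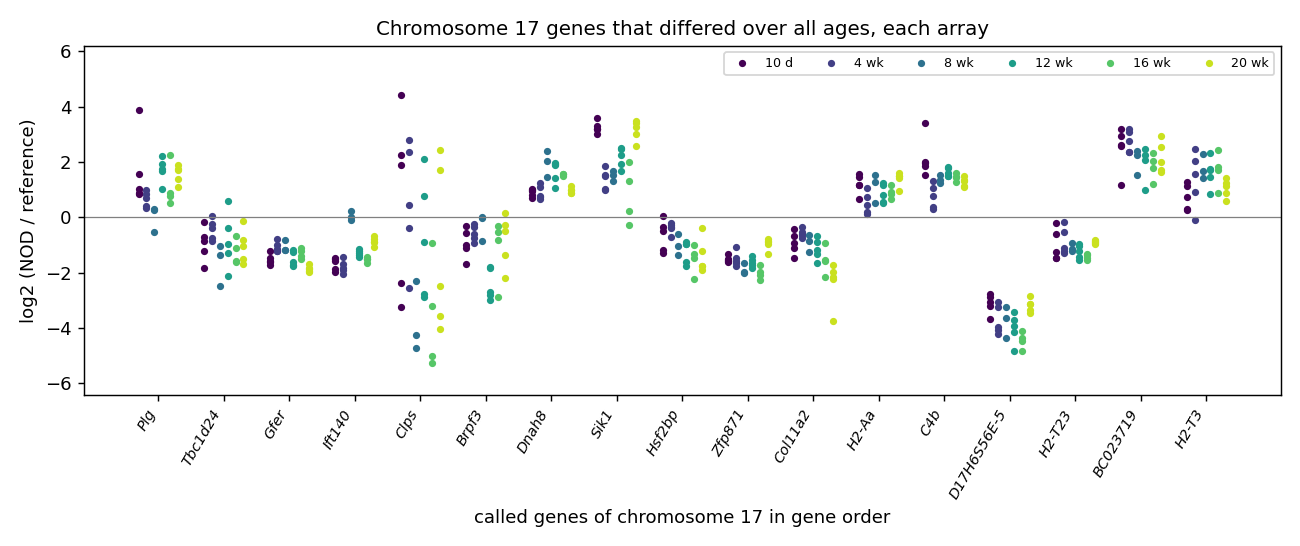
Log2 ratio of NOD over reference (vertical axis) on each array for the 17 chromosome 17 genes that differed over all ages, in gene order (horizontal axis), with 1 point per array coloured by age. D17H6S56E-5 lay below 0 on every array with a mean of -3.70, C4b lay above 0 on every array with a mean of 1.45, and Clps, a pancreatic gene, spread to both sides of 0.

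Genes of the exocrine pancreas were lower in NOD on average over the ages, with a wide spread between arrays. The digestive enzyme genes Cpb1 (log2 -2.41 ± 0.74), Cela3b (-1.90), Pnliprp1 (-1.89), Pnlip (-1.88) and Prss3 (-1.75) and the secreted pancreatic proteins Reg1 (-2.04) and Reg2 (-2.03 ± 0.48) all passed, but each was lower on only 16 to 19 of 27 arrays. Amy1 and Ctrc passed too, with a red dye saturated on 12 and 3 of 27 arrays and a green dye saturated on 5 for Amy1, so the size of their ratios was not measured. Of 24 list members 17 passed, 23 when adjusted over the list alone, and the median was -1.37 (-1.54 with the campaign block). The list's camera adjusted p was 0.013, and the adjusted p = 0.83 with an estimated correlation. Genes of mitosis (G2 and M phase) had a median of -0.51, with 0 of 28 past the 2-fold minimum and 27 lower when adjusted over the list alone (adjusted p = 0.77 with an estimated correlation). Aurkb, a mitotic kinase, was at -0.84 ± 0.07.

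**Figure D2:**
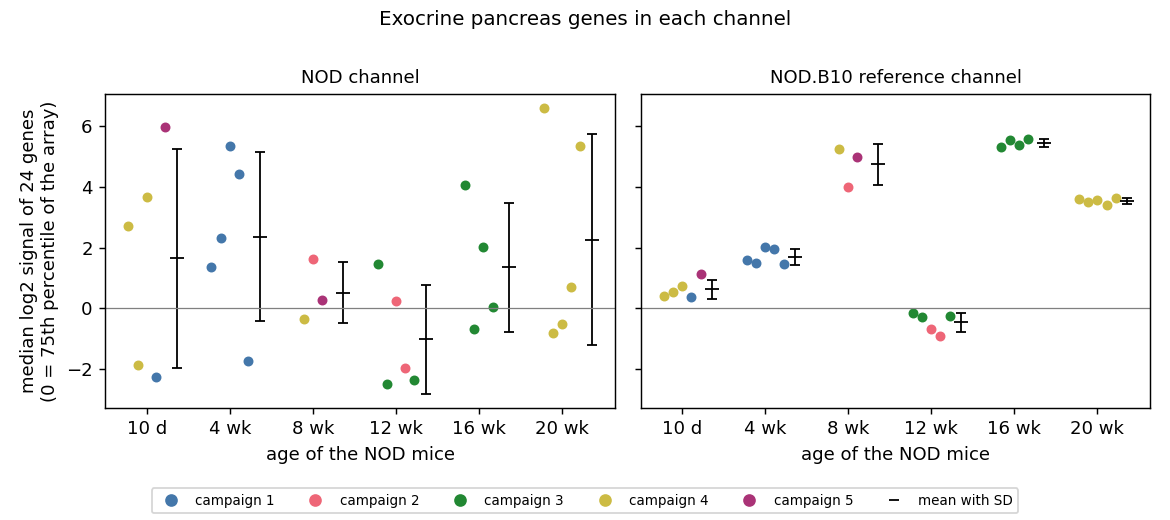
Median log2 signal of 24 exocrine pancreas genes (vertical axis, 0 is the 75th percentile of the array) by age of the mice (horizontal axis), in the NOD dye and in the reference dye, with 1 point per array coloured by scan campaign and the mean with SD beside each age. The reference lay between 5.31 and 5.58 at 16 weeks and between -0.91 and -0.16 at 12 weeks, and the NOD dye at 20 weeks spread from -0.83 to 6.59.

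At 10 days, before islet inflammation is usually seen in this strain, genes of B cells were higher and granulocyte genes lower in NOD. Tnfrsf13c, the receptor for the B cell survival factor BAFF, was at log2 1.25 ± 0.12 (n = 5, 5 of 5 arrays). Of 19 B cell genes 2 were higher, 17 when adjusted over the list alone, with a median of 0.62 (0.70 with the campaign block, adjusted p = 0.071 with an estimated correlation). Elane, the neutrophil elastase, was at -1.46 ± 0.16. Of 18 neutrophil genes 6 were lower, 16 when adjusted over the list alone (median -0.86, -0.63 with the block, adjusted p = 0.071 with an estimated correlation). The basophil protease gene Mcpt8 was at -1.93 ± 0.31. Of 17 genes of mast cells, basophils and eosinophils 8 were lower (9 when adjusted over the list alone, median -0.91, -0.97 with the block, adjusted p = 0.073 with an estimated correlation). Among genes named by the rule the highest ratios were those of Sik1 at 3.27 ± 0.21, C4b at 2.16 ± 0.17 and Ambp at 2.02 ± 0.62. Those with the lowest were Dct, an enzyme of melanin synthesis, at -4.36 ± 0.43 (NOD dye well above background on 3 of 5 arrays), D17H6S56E-5 at -3.11 and Scgb1b27, a secretoglobin whose NOD dye was well above background on 2 of 5 arrays.

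The 10-day test gave 271 genes, 107 higher and 164 lower, and 379 with the campaign block, 147 of them shared. Normexp gave 68, of which 57.4% were higher against 39.5%. Without replicate 4, the array scanned with the 4-week samples, it gave 535. Ambp did not pass with the block (adjusted p = 0.10).

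At 4 weeks, 650 genes differed, 428 higher and 222 lower. Fa2h, a fatty acid hydroxylase, was 123-fold higher (log2 6.94 ± 0.72, adjusted p = 6.2e-07, 5 of 5 arrays), Nlrx1 52.3-fold (5.71 ± 0.59, 1.87 with the mean of its probes) and Insc, a regulator of spindle orientation, 39.9-fold (5.32 ± 0.67). With scan campaign as a block these values were 1.09 for Fa2h (adjusted p = 0.72), 0.44 for Nlrx1 and -1.15 for Insc. There 45 genes passed, 30 of them shared, and 35.6% were higher against 65.8% without the block. The block values of 4 weeks rest on the single 10-day array of campaign 1, on which Nlrx1 stood at 6.88. Normexp gave 88 genes, 85.2% of them higher. D17H6S56E-5 was at -3.71 (-3.88 with the block). Lipn, a lipase, was at least 3.12-fold lower, and Tnfsf9, a costimulatory ligand, was at least 3.36-fold lower. S phase genes had a median of -0.62 (-0.42 with the block), with 0 of 23 past the 2-fold minimum and 20 lower when adjusted over the list alone (adjusted p = 0.68 with an estimated correlation). Their members Cdt1, a factor of replication licensing, and Ung, a uracil glycosylase, were at -0.63 and -0.62.

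**Figure D3:**
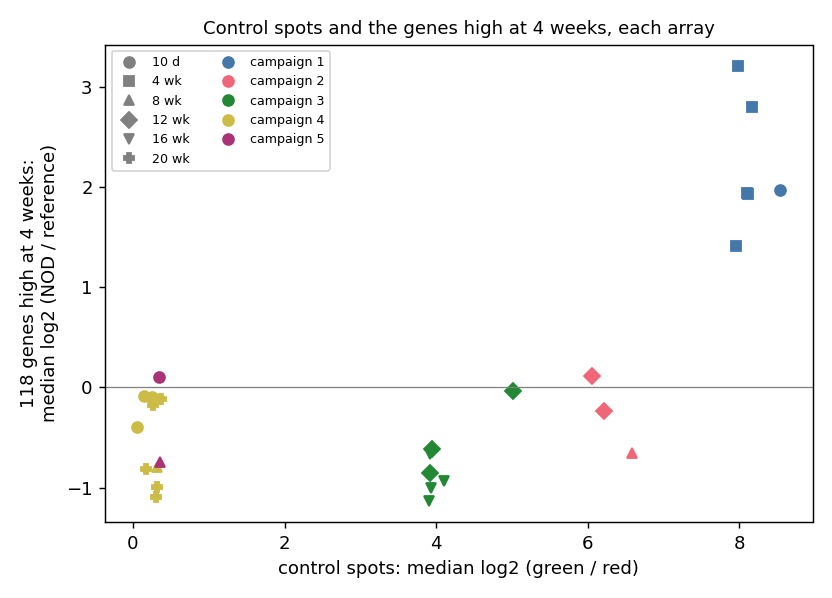
Median log2 ratio of the 118 genes, 30 of them exocrine pancreas genes or genes following these, that were higher at 4 weeks than at 16 and 20 weeks by over 2 (vertical axis) against the median log2 of green over red signal of positive control spots (horizontal axis), with 1 point per array, shaped by age and coloured by scan campaign. The 4-week arrays and the 10-day array of campaign 1 had control ratios of 7.96 to 8.54 and stood apart from campaign 4, which had 0.06 to 0.37.

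At 8 weeks, 597 genes differed, 93 higher and 504 lower, 680 with the campaign block and 90 with normexp. Exocrine pancreas genes were among the lowest: Reg2 at log2 -5.58 ± 1.40, Cela3b at -5.39 ± 1.83 and Prss3 at -5.11 ± 1.63 (n = 3, 3 of 3 arrays). Of 24 list members 13 passed and 24 did when adjusted over the list alone, with a median of -4.26 (-5.75 with the block, adjusted p = 0.55 with an estimated correlation). Regulatory and activated T cell genes had a median of -0.56 (-0.61 with the block), with 0 of 16 past the 2-fold minimum and 8 lower when adjusted over the list alone (adjusted p = 0.31 with an estimated correlation). Tnfrsf4, a costimulatory receptor, was at -0.89 ± 0.14. Adipose genes had a median of -0.72 (-0.68 with the block), with 1 of 14 lower and 3 when adjusted over the list alone (adjusted p = 0.64 with an estimated correlation). That gene was Fabp4, a fatty acid binding protein, at -1.56 ± 0.29. Of the genes named by the rule Dnah8 was highest at 1.98 ± 0.16 (0.31 with the mean of its probes, which did not pass), and H2-T3 and Trpd52l3 were at least 1.97-fold and 2.27-fold higher.

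At 12 weeks, genes of red cell formation and cell division were lower in NOD and genes of smooth muscle higher. Erythroid genes had a median of -1.69, 25 of 27 lower and 25 when adjusted over the list alone (-2.15 with the block, adjusted p = 0.34 with an estimated correlation). One of them, the transferrin receptor gene Tfrc, was at -2.21 ± 0.20 (n = 5). For G2 and M phase 22 of 28 genes were lower, 28 when adjusted over the list alone (median -1.46, -1.66 with the block). Nusap1, a spindle protein, was at -2.07. For S phase 17 of 23 were lower, 23 when adjusted over the list alone (median -1.18, -1.31 with the block). The ribonucleotide reductase Rrm2 was at -1.83. Both division lists had an adjusted p = 0.34 with an estimated correlation. Genes of smooth muscle and reticular cells had a median of 1.09 (1.04 with the block) and 8 of 14 were higher, 13 when adjusted over the list alone. Tagln, an actin-binding protein of smooth muscle, was at 2.01 ± 0.14, and the list held at adjusted p = 0.017 with an estimated correlation.

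Smaller shifts at 12 weeks were seen in genes of macrophages (median 0.55, 0.77 with the block, 1 of 20 higher, 15 when adjusted over the list alone), stroma (0.51, 0.44 with the block, 2 of 22 higher, 13 when adjusted over the list alone) and NF-kB and stress response (0.50, 0.44 with the block, 1 of 27 higher, 19 when adjusted over the list alone). All 3 had an adjusted p = 0.34 with an estimated correlation. The complement gene C1qa was at 1.14 ± 0.10, the laminin gene Lamc1 at 0.99 and the early response gene Jund at 0.86. Ccl24 at 2.34 ± 0.39, Sik1 at 2.17 ± 0.21 and Clec2d, a ligand of an inhibitory natural killer cell receptor, at 2.14 ± 0.18 had the highest ratios. The lowest of the named genes were D17H6S56E-5 at -4, the linker histone H1f5 at -3.22 ± 0.25 and Apol10a at -3.04 ± 0.30. In all 1520 genes differed, 367 higher and 1153 lower, and 896 with the campaign block, where Ccl24 was lost (adjusted p = 0.076). With normexp 341 did, and the share of higher genes went from 24.1% to 12%.

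At 16 weeks the neutrophil list was lower and the smooth muscle list again higher. S100a8, a calcium-binding protein abundant in neutrophils, was at log2 -2.37 ± 0.17 and the cathelicidin gene Camp at -1.97 ± 0.18 (n = 4, 4 of 4 arrays). Of 18 neutrophil genes 11 were lower, 16 when adjusted over the list alone (median -1.06, -1.37 with the block, adjusted p = 0.20 with an estimated correlation). Smooth muscle genes had a median of 1 (0.76 with the block) with 7 of 14 higher, 13 when adjusted over the list alone. They held at adjusted p = 0.030 with an estimated correlation. All 24 of 24 exocrine pancreas genes were lower, also when adjusted over the list alone, with a median of -4 (-6.32 with the block, adjusted p = 0.58 with an estimated correlation). The lowest were Cpb1 at -6.04 ± 1.88, Reg2 at -6.01 ± 1.22 and Reg1 at -5.60 ± 1.69. These 3 genes did not pass with the block (Reg2 adjusted p = 0.14).

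Erythroid genes at 16 weeks had a median of -0.71 (-1.29 with the block), with 6 of 27 lower and 14 when adjusted over the list alone (adjusted p = 0.68 with an estimated correlation). G2 and M phase genes had a median of -0.77 (-1.13 with the block), with 7 of 28 lower and 24 when adjusted over the list alone (adjusted p = 0.57 with an estimated correlation). S phase genes had a median of -0.54 (-0.91 with the block), with 0 of 23 past the 2-fold minimum and 13 lower when adjusted over the list alone (adjusted p = 0.63 with an estimated correlation). Macrophage genes had a median of 0.50 (0.72 with the block), 3 of 20 higher and 13 when adjusted over the list alone. Mast cell, basophil and eosinophil genes had -0.60, 5 of 17 lower and 10 when adjusted over the list alone. These last lists had an adjusted p = 0.41 with an estimated correlation, and the mast cell list was lost with the block at -0.25. Adipose genes had a median of 0.53 with 2 of 14 higher, 3 when adjusted over the list alone (adjusted p = 0.58 with an estimated correlation), and 0.26 with the block, no longer past the test. Clec2d at 2.68 ± 0.20, Lrrc3b at 2.53 ± 0.17 and the olfactory receptor gene Olfr1497 at 2.41 ± 0.19 were among the highest. The total was 1626 genes, 460 higher and 1166 lower, and 164 with the campaign block, 103 of them shared, where the share of higher genes was 48.2% against 28.3%. Normexp gave 198.

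At 20 weeks, when many females of this strain are diabetic, neutrophil and erythroid genes were higher in NOD. Ngp, a neutrophil granule protein, was at log2 2.66 ± 0.13 (6.32-fold, adjusted p = 1.5e-13, 5 of 5 arrays) and Camp at 1.92 ± 0.16. Of 18 neutrophil genes 9 were higher, 12 when adjusted over the list alone (median 0.96, 1.16 with the block). The beta globin gene Hbb-bt was at 1.80 ± 0.23 and the erythroid gene Trim10 at 1.88 ± 0.25. Of 27 erythroid genes 13 were higher, 22 when adjusted over the list alone (median 0.91, 1.07 with the block). Regulatory and activated T cell genes were lower, 5 of 16 and 12 when adjusted over the list alone (median -0.59, -0.64 with the block). The costimulatory receptor Tnfrsf9 was at -2.97 ± 0.20, with the NOD dye well above background on 2 of 5 arrays, and Ikzf2, which encodes the transcription factor Helios, at -1.74 ± 0.13 (-0.46 with the mean of its probes, which did not pass). Each of these 3 lists had an adjusted p = 0.96 with an estimated correlation. Sik1 at 3.15 ± 0.21 and Ppp1r15a, a stress-induced phosphatase subunit, at 2.53 ± 0.17 were also high. The olfactory receptor gene Olfr175 at -3.38 ± 0.15 (NOD dye above background on 4 of 5 arrays) was lowest of the named genes with Plppr4, at least 8.46-fold lower, and Olfr1134, whose NOD dye was well above background on 2 of 5 arrays. The total was 3185 genes, 1114 higher and 2071 lower, and 2723 with the campaign block, 2014 of them shared. With normexp 279 passed, and most of these were higher (57% against 35%).

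**Figure D4:**
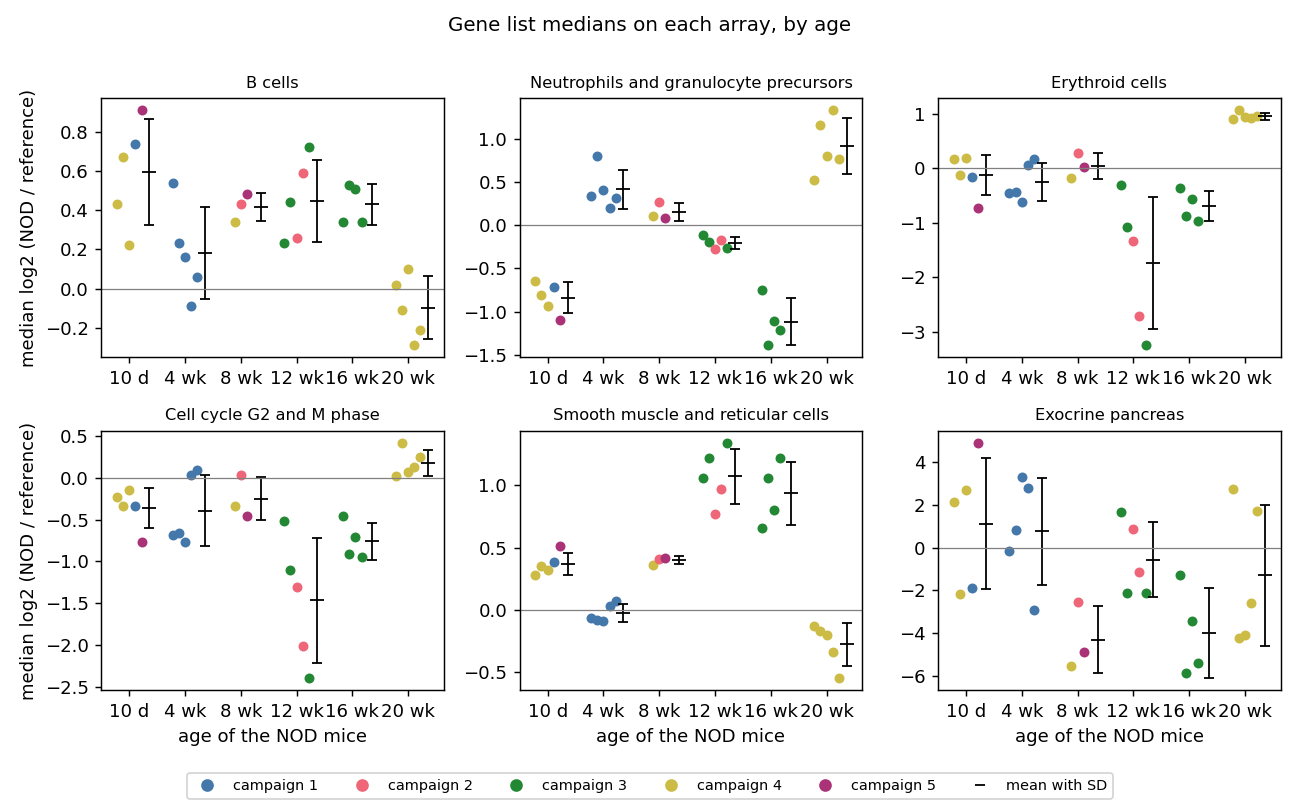
Median log2 ratio of NOD over reference (vertical axis) of 6 gene lists by age of the mice (horizontal axis), with 1 point per array coloured by scan campaign and the mean with SD beside each age. Neutrophil genes lay between -1.10 and -0.64 at 10 days and between 0.52 and 1.33 at 20 weeks, erythroid genes at 12 weeks spread from -3.25 to -0.31, and exocrine pancreas genes spread to both sides of 0 at 4 of the 6 ages.

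Ages were compared in turn by ratio, which either strain can move. From 10 days to 4 weeks the ratio of neutrophil genes rose, 14 of 18 and 15 when adjusted over the list alone, with a median change of 1.38 (adjusted p = 0.050 with an estimated correlation). It was 1.25 with the campaign block, which here is the same contrast as within campaign 1, against a single 10-day array. In the NOD dye alone, across campaigns, these genes fell (median -0.89, camera adjusted p = 0.00065). Ratios of NF-kB and stress response genes fell, 13 of 27 and 17 when adjusted over the list alone (median -0.59, -0.45 with the block, adjusted p = 0.087 with an estimated correlation). Among them was the early response gene Fos at -2.36 ± 0.30. Ch25h, an oxysterol-producing enzyme outside that list, was at -2.08 ± 0.23. Genes of megakaryocytes rose (8 of 17, 9 when adjusted over the list alone, median 0.54, 0.29 within campaign 1, adjusted p = 0.25 with an estimated correlation). Genes of mast cells, basophils and eosinophils rose too (6 of 17, 8 when adjusted over the list alone, median 0.76, 0.59 within campaign 1, adjusted p = 0.10 with an estimated correlation). Smooth muscle genes fell (5 of 14, 10 when adjusted over the list alone, median -0.61, -0.57 within campaign 1, adjusted p = 0.087 with an estimated correlation). Adipose genes fell (2 of 14, also when adjusted over the list alone, median -0.54, adjusted p = 0.36 with an estimated correlation) but not within campaign 1 (-0.17). In the NOD dye alone the medians of megakaryocyte and adipose genes were -0.10 and 0.44, against the direction of the ratio, and that of mast cell genes was 0.14 and did not pass (camera adjusted p = 0.68).

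Single genes from 10 days to 4 weeks numbered 2666, 1348 higher and 1318 lower. Of all genes tested 2637 did not overlap array by array (0.794% by chance). Among the named genes, whose ages do not overlap, the highest changes were those of Dct (3.33 ± 0.60, -1.11 in the NOD dye alone, which was well above background on 5 of 10 arrays), Scgb1b27 (3.04 ± 0.51, NOD dye above background on 7 of 10) and Sema4g, whose reference dye was well above background on 3 of 10 arrays. The heat shock gene Hspa1a (-2.74 ± 0.47), Fos and Ch25h were among the lowest. Only 1 gene passed with the campaign block and 1 within campaign 1, where a single 10-day array stands against the 5 of 4 weeks. There Dct stood at 2.70 (adjusted p = 0.54) and Fos at -2.13 (0.15 as adjusted p).

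From 4 to 8 weeks 4707 genes changed, 2202 higher and 2505 lower, but 10 with the campaign block. Of all genes 6602 did not overlap (3.57% by chance). Fa2h fell by 7.68 ± 1.17 on the log2 scale (adjusted p = 0.00012), although its NOD dye was well above background on only 1 and its reference dye on 2 of 3 arrays of 8 weeks, and with the block it was at -0.23 (adjusted p = 0.98). Heat shock genes rose, 11 of 16 and 11 when adjusted over the list alone (median 0.98, 0.84 with the block, adjusted p = 0.073 with an estimated correlation). Among them was Hspa1a at 2.55 ± 0.54. S phase genes rose, 16 of 23 and 19 when adjusted over the list alone (median 0.89, 0.92 with the block, adjusted p = 0.54 with an estimated correlation). Exocrine pancreas genes fell, 10 of 24 and 24 when adjusted over the list alone (median -5.22, -10.09 with the block, adjusted p = 0.70 with an estimated correlation). Stroma genes rose, 9 of 22 and 10 when adjusted over the list alone (0.59, 0.68 with the block, adjusted p = 0.42 with an estimated correlation). Smooth muscle genes rose, 8 of 14 (8 when adjusted over the list alone, 0.52, 0.50 and lost with the block, adjusted p = 0.43 with an estimated correlation). Regulatory and activated T cell genes fell, 4 of 16 (4 when adjusted over the list alone, -0.54, -0.76 with the block, adjusted p = 0.46 with an estimated correlation). Class II presentation genes rose, 7 of 16 (8 when adjusted over the list alone, 0.53, 0.22 and lost with the block, adjusted p = 0.77 with an estimated correlation). The NOD dye alone gave S phase and regulatory T cell genes medians of -0.14 and 0.22, against the direction of the ratio. All block values of this comparison rest on the single 10-day array of campaign 1, which links 4 weeks to the other ages.

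From 8 to 12 weeks erythroid and cell division ratios fell. Of 27 erythroid genes 23 fell, 24 when adjusted over the list alone, with a median of -1.79 and -2.41 within campaign 2 (adjusted p = 0.24 with an estimated correlation). All 23 of 23 S phase genes fell, also when adjusted over the list alone (median -1.46, -1.91 within campaign 2, adjusted p = 0.23 with an estimated correlation). Of 28 G2 and M phase genes 20 fell, 23 when adjusted over the list alone (-1.21, -1.68 within campaign 2, adjusted p = 0.30 with an estimated correlation). H1f5 (-3.41 ± 0.41), Trim37 (-2.74 ± 0.26) and Redrum (-2.65 ± 0.52), an erythroid noncoding RNA, fell. Within campaign 2, against a single 8-week array, they stood at -4.24, -3.27 and -3.36. Slc23a1, a vitamin C transporter, rose by 2.67 ± 0.43 (2.94 within campaign 2). Ighg1, an immunoglobulin heavy chain, rose by 2.95 ± 0.74 (3.03 within campaign 2). The single 8-week array of campaign 2 gives no spread of its own, so these values were not tested there. Apol10a (-3.45 ± 0.48) and Apol10b (-3.29 ± 0.52) stood at -2.44 and -2.32 within campaign 2.

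Other lists also rose from 8 to 12 weeks. Genes of the NF-kB and stress response did so (14 of 27, 17 when adjusted over the list alone, median 0.65, 0.73 within campaign 2, adjusted p = 0.19 with an estimated correlation). So did those of macrophages (11 of 20, 13 when adjusted over the list alone, 0.54, 0.80, adjusted p = 0.24 with an estimated correlation) and smooth muscle (7 of 14, 9 when adjusted over the list alone, 0.62, 0.49, adjusted p = 0.17 with an estimated correlation). The last were those of plasma cells (5 of 12, 5 when adjusted over the list alone, 0.50, 0.36, adjusted p = 0.43 with an estimated correlation) and adipose tissue (4 of 14, 8 when adjusted over the list alone, 0.91, 0.68, adjusted p = 0.31 with an estimated correlation). Exocrine pancreas genes had a median of 3.68, with 1 of 24 past the test and 0 when adjusted over the list alone (2.25 within campaign 2, where the list was lost, -1.39 in the NOD dye alone, adjusted p = 0.56 with an estimated correlation). Of all genes 6903 did not overlap (3.57% by chance), and 4497 changed, 2245 higher and 2252 lower. There were 945 with the block and 1145 within campaign 2, where a single 8-week array is assumed to vary like the others.

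From 12 to 16 weeks 207 genes changed, 55 higher and 152 lower, and 1806 of all did not overlap (1.59% by chance). S100a8 fell by 1.74 ± 0.22 (adjusted p = 0.00063). Of 18 neutrophil genes 9 fell, 14 when adjusted over the list alone, with a median of -0.94 (-0.98 within scan day 5) and adjusted p = 0.047 with an estimated correlation. Erythroid genes had a median of 1.01 (1 of 27 higher, 22 when adjusted over the list alone, 0.83 within the day, adjusted p = 0.32 with an estimated correlation). S phase genes had a median of 0.72 (0 of 23 past the test, 13 when adjusted over the list alone, 0.51 within the day) and G2 and M phase genes 0.67 (0 of 28, 7 when adjusted over the list alone, 0.57 within the day), both with adjusted p = 0.32 and an estimated correlation. Exocrine pancreas genes had a median of -3.41 (0 of 24, 3 when adjusted over the list alone, -3.18 within the day, adjusted p = 0.40 with an estimated correlation). In the NOD dye alone the median was 2.33, but array values overlapped. Pla2g1b, a pancreatic phospholipase, was at -2.63 ± 0.52 (0.90 in the NOD dye alone) and Crem, a cyclic AMP responsive regulator, at -2.08 ± 0.40 (0.11). Within scan day 5 (3 against 4 arrays) limma called 0 genes, with 2182 at an unadjusted p under 0.05 against 1300 by chance. The campaign block called 11, normexp 402, array weights 584 and a fit of these ages only 1.

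From 16 to 20 weeks neutrophil and erythroid ratios rose together with heat shock and cell division genes. Ngp rose by 3.79 ± 0.19, S100a8 by 3.79 ± 0.22 and Camp by 3.88 ± 0.24 (n = 9). Of 18 neutrophil genes 15 rose, 15 when adjusted over the list alone (median 1.89, 2.31 with the block, adjusted p = 0.11 with an estimated correlation). Of 27 erythroid genes 23 rose, 25 when adjusted over the list alone (1.60, 2.49 with the block, adjusted p = 0.51 with an estimated correlation). For G2 and M phase 18 of 28 rose, 20 when adjusted over the list alone (1.02, 1.35 with the block, adjusted p = 0.62 with an estimated correlation). For S phase 12 of 23 rose, 14 when adjusted over the list alone (0.71, 1.06 with the block, adjusted p = 0.76 with an estimated correlation). For heat shock 9 of 16 rose, 11 when adjusted over the list alone (0.54, 0.67 with the block, adjusted p = 0.21 with an estimated correlation). H1f5 rose by 3.91 ± 0.38. Olfr1497 (-5.53 ± 0.26), Lrrc3b (-5.08 ± 0.23), Spry2 (-4.90 ± 0.28), an inhibitor of growth factor signalling, Olfr175 (-4.36 ± 0.22) and Chrne (-3.97 ± 0.18), a subunit of the muscle acetylcholine receptor, fell. Each of these kept its call with the campaign block except Reg2, at 4.88 ± 1.63 and 9.68 (adjusted p = 0.23).

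Other lists fell from 16 to 20 weeks. Among them were those of smooth muscle (10 of 14, 10 when adjusted over the list alone, median -0.89, -0.66 with the block, adjusted p = 0.11 with an estimated correlation) and stroma (14 of 22, 15 when adjusted over the list alone, -0.84, -0.74 with the block, adjusted p = 0.42 with an estimated correlation). Genes of B cells fell (11 of 19, 11 when adjusted over the list alone, -0.57, -0.22 and lost with the block, adjusted p = 0.62 with an estimated correlation). So did those of islet (6 of 16, 8 when adjusted over the list alone, -0.64, -0.72 and lost with the block, adjusted p = 0.42 with an estimated correlation) and adipose tissue (5 of 14, 5 when adjusted over the list alone, -0.89, -0.70 and lost with the block, adjusted p = 0.70 with an estimated correlation). Exocrine pancreas genes had a median of 2.59 with 3 of 24 higher and 0 when adjusted over the list alone (5.96 with the block, adjusted p = 0.84 with an estimated correlation). In all 9021 genes changed, 3778 higher and 5243 lower, and 627 with the campaign block. Of all genes 7039 did not overlap (1.59% by chance). The ages shared no scan campaign, so no value within a campaign can be had.

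Between 4 and 20 weeks 7409 of all genes did not overlap (0.794% by chance), and 11067 changed, 4226 higher and 6841 lower. With the campaign block 1062 did, 1050 of them shared. Fam117a (2.66 ± 0.19), the small GTPase gene Arf5 (2.63 ± 0.16), Ppp1r15a (2.61 ± 0.24) and Dhrs11 (2.18 ± 0.25) rose and kept their calls with the block. Fa2h (-8.16 ± 1.01), Nlrx1 (-5.36 ± 0.84) and Oosp1 (-5.12 ± 0.67), among the genes that fell most, did not, at -0.29, 1.64 and 0.19, and Nlrx1 was at -2.02 with the mean of its probes. At 20 weeks the NOD dye of Fa2h was well above background on 1 and its reference dye on 2 of 5 arrays, so the size of its fall rested mostly on dim signals. Insc fell too, but neither of its dyes was well above background on any array of 20 weeks, so the size was not measured. Block values of this comparison rest on the single 10-day array of campaign 1, which links 4 weeks to the other ages. Erythroid genes rose (23 of 27, 23 when adjusted over the list alone, median 1.24, 1.07 with the block). Genes of heat shock rose too (10 of 16, 10 when adjusted over the list alone, 0.75, 0.69 with the block, adjusted p = 0.48 with an estimated correlation), as did those of S phase (14 of 23, 17 when adjusted over the list alone, 0.72, 0.67), G2 and M phase (12 of 28, 12 when adjusted over the list alone, 0.62, 0.46) and neutrophils (8 of 18, 9 when adjusted over the list alone, 0.57, 0.64). Type I interferon response genes fell (18 of 29, 19 when adjusted over the list alone, -0.62, -0.62 with the block). So did those of natural killer cells (12 of 19, 12 when adjusted over the list alone, -0.80, -0.53 and lost with the block) and regulatory and activated T cells (10 of 16, 10 when adjusted over the list alone, -0.70, -0.60). Diabetes candidate genes outside H2 fell (10 of 19, 11 when adjusted over the list alone, -0.56, -0.56). Measured in the NOD dye alone, natural killer cell, type I interferon and candidate genes had medians of 0.37, 0.10 and 0.29, against the direction of the ratio. Regulatory T cell genes had an adjusted p = 0.92 with an estimated correlation, and all lists of this comparison without a stated value had an adjusted p = 1 with an estimated correlation.

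A change of any kind from 4 to 20 weeks was found for 14798 genes with the F test and for 3844 with the campaign block. Wide ranges of age means were those of Fa2h (8.16 on the log2 scale, from 4 to 20 weeks, where its signals were dim), Reg2 (6.81) and the trypsin gene Prss3 (6.11), all highest at 4 weeks. That of Insc (6.52) rested on 8-week arrays on which neither dye was well above background. Reg3b (6.03, NOD dye above background on 1 of 3 arrays of 8 weeks), Spink1 (5.99), Sycn (5.97) and Try5 (5.43), pancreatic genes, and Nlrx1 (5.44) were also highest at 4 weeks. Olfr1497 (5.53, adjusted p = 8.7e-13) was highest at 16 weeks. With the block Olfr1497 kept its range at 5.57 (adjusted p = 2.3e-05), Reg2 and Reg3b kept their calls, and Fa2h dropped to 0.41.

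Between 10 days and 20 weeks, ages that share scan day 6, the ratio of NOD over reference rose for neutrophil genes. On that day the reference dye fell (median -1.66) while the NOD dye had a median of 0.18, with 3 of 18 genes higher and 2 lower. The ratio of Ngp rose by 3.53 ± 0.18 (11.6-fold, adjusted p = 1.1e-11) and by 3.45 within the day, Elane by 2.70 ± 0.23 (2.64 within the day) and Camp by 2.69 ± 0.23 (2.68). Anxa1, an annexin, rose by 2.85 ± 0.16 (2.85), Lcn2, the lipocalin of neutrophil granules, by 2.45 ± 0.23 (2.30) and the granule protease gene Ctsg by 2.44 ± 0.24 (2.40). In the NOD dye alone, over all arrays of both ages, Camp, Anxa1 and Ctsg stood at -0.26, -0.21 and -0.47. Of 18 neutrophil genes 14 rose in ratio, 15 when adjusted over the list alone, with a median of 1.85, 1.73 with the campaign block and 1.74 within the day (adjusted p = 0.15 with an estimated correlation, and adjusted p = 0.39 within the day). Erythroid genes rose in ratio, 17 of 27 and 22 when adjusted over the list alone (1.07, 0.90 within the day, adjusted p = 0.55 with an estimated correlation). G2 and M phase genes rose in ratio, 13 of 28 and 14 when adjusted over the list alone (0.62, 0.52 within the day, adjusted p = 0.65 with an estimated correlation), while both erythroid and G2 and M phase genes fell in each dye on scan day 6 (medians -0.52 and -1.07 in NOD, -1.46 and -1.50 in the reference). B cell genes fell in ratio, 12 of 19 and 13 when adjusted over the list alone (-0.71, -0.57 within the day). T cell genes fell in ratio, 15 of 21 and 15 when adjusted over the list alone (-0.65, -0.44). Those of the type I interferon response fell in ratio, 15 of 29 and 15 when adjusted over the list alone (-0.64, -0.51), and each of these had an adjusted p = 0.55 with an estimated correlation. On scan day 6 the medians of B cell, T cell and type I interferon genes were above 0 in each dye (0.62, 1.49 and 0.22 in NOD, 0.64, 1.97 and 0.70 in the reference). Slit1 (-3.02 ± 0.17, NOD dye above background on 3 of 5 arrays of 20 weeks), an axon guidance ligand, Sorl1 (-2.76 ± 0.27), a sorting receptor, and Tnfrsf9 (-2.64 ± 0.28, NOD dye above background on 2 of 5 arrays of 20 weeks) fell, at -2.89, -2.46 and -2.53 within the day.

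Further lists whose ratio fell from 10 days to 20 weeks were those of regulatory and activated T cells (8 of 16, 10 when adjusted over the list alone, median -0.61, -0.61 within the day, adjusted p = 0.53 with an estimated correlation) and natural killer cells (10 of 19, 10 when adjusted over the list alone, -0.72, -0.33). So did those of smooth muscle (10 of 14, 10 when adjusted over the list alone, -0.81, -0.62), adipose tissue (5 of 14, 5 when adjusted over the list alone, -0.69, -0.72) and islet (9 of 16, 9 when adjusted over the list alone, -0.74, -0.62 and lost within the day). Regulatory T cell, natural killer cell and adipose genes were above 0 in each dye on scan day 6 (medians 0.48, 1.44 and 0.93 in NOD, 1.58, 1.74 and 1.47 in the reference). The islet list had an adjusted p = 0.53 with an estimated correlation and the others 0.55 as adjusted p. Of all genes 6253 did not overlap (0.794% by chance), and 8811 changed, 3083 higher and 5728 lower. There were 6738 with the campaign block and 4842 within the day (1964 higher, 2878 lower). Each of the 20 genes named by rule for this comparison passed within the day.

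Because those arrays share a scan day, each dye could be compared between 10 days (3 arrays) and 20 weeks (5 arrays) on its own, an addition made after the data were examined. In the NOD dye 4808 genes changed, 2049 higher and 2759 lower at 20 weeks. In the reference dye 8968 did, 4933 higher and 4035 lower. The antibody genes Ighg1 (log2 5.27 ± 1.07 in NOD, 5.20 ± 0.12 in the reference) and Jchain (4.14 ± 0.17 and 4.15 ± 0.16) rose in both strains. So did Ubd, an interferon-inducible ubiquitin-like protein (3.04 ± 0.26 and 3.88 ± 0.16), and the class II gene H2-Eb1 (2.76 ± 0.27 and 2.39). The cystatin family genes Cstdc6 (-7.89 ± 0.33 and -7.72 ± 0.13) and Stfa2l1 (-6.22 ± 0.36 and -7.20 ± 0.15) fell in both. So did the eosinophil peroxidase gene Epx (-3.31 ± 0.33 and -4.67 ± 0.13), the matrix genes Mfap2 (-4.31 ± 0.33 and -3.99 ± 0.16) and Col1a1 (-3.96 ± 0.28 and -1.82), and Vpreb1, a component of the pre-B cell receptor (-5.12 ± 0.19 in the reference, -5.56 in NOD, where it was above background on 5 of 8 arrays). Sycn, a protein of pancreatic secretory granules, rose in the reference (4.6 ± 0.13) and stood at 1.13 in NOD (adjusted p = 0.74).

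By lists, T cell genes rose in both dyes, 17 of 21 in NOD (19 when adjusted over the list alone, median 1.49) and 20 of 21 in the reference (21 when adjusted over the list alone, 1.97). Plasma cell genes rose, 9 of 12 in both (10 and 9 when adjusted over the list alone, 1.41 and 1.27), and so did class II presentation genes, 10 of 16 and 13 of 16 (10 and 13 when adjusted over the list alone, 1.39 and 1.63). Stroma genes fell, 14 of 22 and 16 of 22 (17 in both when adjusted over the list alone, -1.51 and -1.28). So did S phase genes, 18 of 23 and 23 of 23 (22 and 23 when adjusted over the list alone, -1.22 and -1.52), and G2 and M phase genes, 18 of 28 and 28 of 28 (20 and 28 when adjusted over the list alone, -1.07 and -1.50). Erythroid genes fell by a median of 0.52 in NOD (7 of 27, 7 when adjusted over the list alone) and by 1.46 in the reference (24 of 27, 24 when adjusted over the list alone). Neutrophil genes fell in the reference, 14 of 18 (14 when adjusted over the list alone, -1.66), while in NOD 3 of 18 were higher and 2 lower. Exocrine pancreas genes rose in the reference, 23 of 24 (23 when adjusted over the list alone, 2.62), while in NOD 0 of 24 passed (median 0.80). Among other lists past the limits in both dyes were natural killer cells (medians 1.44 in NOD and 1.74 in the reference) and macrophages (0.84 and 0.87). Haematopoietic progenitors were another (-0.83 and -0.85). With an estimated correlation these lists held in the reference (adjusted p = 0.018, 0.044 and 0.016) and not in NOD (0.10, 0.24 and 0.19). Whether the strains differ is what the ratio tests. With an estimated correlation, stroma held in both dyes (adjusted p = 0.017 in NOD and 0.0097 in the reference). The T cell (0.064 and 0.0097 as adjusted p), plasma cell (0.10 and 0.015), S phase (0.14 and 0.024), G2 and M phase (0.14 and 0.012) and erythroid lists (0.41 and 0.012) passed in the reference and not in NOD. In the ratio of these arrays, which compares the dyes, these lists except plasma cells passed at the preset correlation. With an estimated correlation none did (adjusted p = 0.39, 0.99, 0.66, 0.43 and 0.39 in that order). Class II presentation held in neither dye (0.23 and 0.088 as adjusted p), and neutrophil and exocrine pancreas genes held in the reference (adjusted p = 0.012 and 0.0097 with an estimated correlation).

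Genes higher in both dyes numbered 1467, against 389 for independent lists of these sizes. Genes lower in both numbered 1934 against 428, and 72 went opposite ways. The changes of both dyes correlated across genes at 0.70 on the same arrays and at a median of 0.46 (0.34 to 0.53) over 30 splits in which each dye came from other arrays. Genes are not independent replicates. The median SD between arrays on that day was 0.20 at 10 days and 0.18 at 20 weeks in the reference dye, against 0.23 and 0.28 in the NOD dye. Whether the control mice were replicated is not recorded, so the p-values and counts of the reference dye cannot be taken beyond these arrays, and its higher count does not show a larger change.

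**Figure D5:**
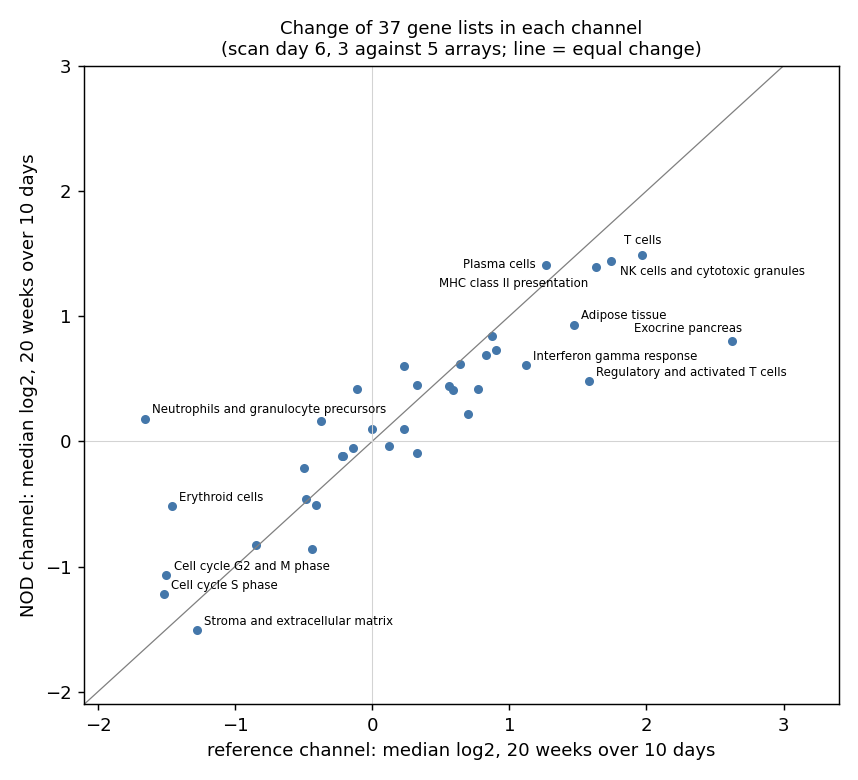
Median log2 change from 10 days to 20 weeks of 37 gene lists in the NOD dye (vertical axis) against the reference dye (horizontal axis), with 1 point per list, 3 against 5 arrays of scan day 6, and a line of equal change. T cell genes lay at 1.49 and 1.97 and stroma genes at -1.51 and -1.28, near the line, while neutrophil genes (-1.66 in the reference) and exocrine pancreas genes (2.62 in the reference) lay away from it.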

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

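The tests of the genes high at 4 weeks, of the exocrine pancreas genes and of chromosome 17 were chosen after these results were seen, as was the comparison of 20 weeks with 10 days.

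Some arrays stood apart from the others of their age by a test for a single distant value, which chance meets in about 1 of 20 groups. It was met by 5 of 72 list medians (6.94%) and by 17 of 283 gene values (6.01%). At 10 days, replicate 5 stood apart with NF-kB and stress response genes at 0.80 (others 0.22 to 0.33), C4b at 3.43 (1.55 to 1.99) and Pnlip at 5.61 (-1.01 to -0.42). It also did so with Ambp at 7.68 (0 to 1.47), Ch25h at 2.25 (1.46 to 1.67), Elane at -1.69 (-1.43 to -1.37), Maob at 3.43 (0.12 to 0.70) and Lrrc3b at -0.44 (0.16 to 0.39). At the same age, replicate 4 had Nlrx1 at 6.88 (-0.26 to 0.08), Tsga8 at 2.72 (0.04 to 0.70) and Mfsd4a at 2.53 (-0.09 to 0.55). Replicate 3 had megakaryocyte genes at -0.46 (-0.20 to -0.13) and replicate 2 had Mucl2 at -1.85 (-3.32 to -2.97). At 4 weeks, Arf5 was at -0.71 in replicate 3 (-0.05 to 0.10), and replicate 5 had Oosp1 at 1.84 (3.45 to 4.01) and Olfr448 at 2.74 (4.72 to 5.22). At 12 weeks, replicate 1 had NF-kB and stress response genes at 0.15 (0.49 to 0.57), and replicate 5 had Trim37 at -2.60 (-2.07 to -1.92) and Fa2h at -2.09 (-0.28 to 0.24). At 16 weeks, mast cell, basophil and eosinophil genes were at -0.89 in replicate 2 (-0.35 to -0.26). At 20 weeks, S phase genes were at 0.42 in replicate 2 (0.09 to 0.13) and H2-Aa was at 0.95 in replicate 3 (1.42 to 1.60).

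At ages that were compared, the difference between NOD and its reference had opposite directions for neutrophil and erythroid genes, and the change itself was tested. Neutrophil genes were lower at 16 weeks and at 10 days and higher at 20 weeks, a difference of 1.89 from 16 to 20 weeks and of 1.85 from 10 days to 20 weeks. Erythroid genes were lower at 16 weeks and higher at 20 weeks, a difference of 1.60. With an estimated correlation these differences had adjusted p = 0.11, 0.15 and 0.51. Adipose genes were lower at 8 weeks (-0.72) and higher at 16 weeks (0.53), and this difference was not tested.

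Control spots, which no comparison uses, had a median log2 of green over red of 8.1 on the 6 arrays of scan campaign 1, where their green signal was saturated, against 6.22 in campaign 2, 3.93 in campaign 3, 0.26 in campaign 4 and 0.35 in campaign 5. In campaigns 4 and 5 their log2 green signal was 6.5 to 6.94, against 6.6 to 7 for negative control spots. The ratio thus ran from background level to saturation and largely followed the campaign.

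Scan campaign and age could both give the set of 118 genes, Fa2h and Nlrx1 among them, that was higher at 4 weeks than at 16 and 20 weeks by over 2 on the log2 scale: in this set the 10-day array of campaign 1 lay above the other 10-day arrays by a median of 1.95, and the 4-week arrays lay above it by 0.41. These medians mix 30 exocrine pancreas genes or genes following these, for which that array lay below the others (-3.75), with 88 other genes, for which it lay above them (2.58) and the 4-week arrays stood 0.08 above it. Over 13 arrays of ages that span campaigns, the set's deviation from its age mean correlated with that of the control ratio at r = 0.828 (1-sided permutation p = 0.0025, 0.012 adjusted over 8 relations; rho = 0.637, permutation p = 0.00036; r = 0.669 without the 2 farthest arrays, 0.405 without that 10-day array), and that of the 88 genes at r = 0.857 (permutation p = 0.003, 0.012 adjusted; rho = 0.676, permutation p = 0.0033; r = 0.66 and 0.655). The kind of control spot was changed after a first result, in which 1106 other spots had given, by their deposited ratio, r = 0.482 and rho = 0.16 (permutation p = 0.053 for both, r = -0.526 without the 2 farthest), while in raw signal they gave r = 0.16 and rho = 0.198 (permutation p = 0.19 and 0.13, r = 0.0509) and 330 spots of another kind r = 0.111 and rho = 0.214 (permutation p = 0.32 and 0.13, r = -0.018), and with the 88 genes these 3 gave r = 0.354, 0.0628 and 0.00146 (permutation p = 0.15, 0.36 and 0.51), rho = -0.104, 0.165 and 0.209 (permutation p = 0.28, 0.079 and 0.069) and r = -0.884, -0.0106 and -0.0972 without the 2 farthest (-0.154, 0.75 and 0.719 without that 10-day array). As 1 relation of 4 passed its test, the others moved with that 10-day array, and this single array links the ages, campaign and age cannot be told apart for these genes.

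Exocrine pancreas genes were lower in NOD than in the reference at 8 and 16 weeks, and pancreatic tissue in some samples is a candidate explanation. In the NOD dye the median pairwise correlation of the 24 genes within ages was 0.91, the highest of 37 lists (ribosomal proteins had 0.79), and the SD of the list median within ages was 2.75. This concerns NOD and cannot tell why the reference dye was high at 8, 16 and 20 and low at 12 weeks. None of the genes is held by another list, and Cela3b and Cpb1, which were not saturated on any array, had mean log2 signals of 13.11 and 12.58 in NOD and 14.65 and 14.63 in the reference. Lower expression in NOD was tested only at 8 and 16 weeks, picked for their low ratio. In the NOD dye these 7 arrays lay at -1 relative to 10 days and 4 weeks (10 arrays, exact permutation p = 0.44). The reference dye was 3.98 higher there, with no valid p as the ages were picked, and its arrays of an age could be repeats of the same control RNA. A missed threshold does not show equal levels, so lower expression in NOD stays open.

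Genes that differed over all ages were concentrated on chromosome 17, where the strains differ by design. Strain variants under single probes and a difference in expression could both give this. Of the 8 such genes with several probes, 12.5% had all probes beyond 1 in size against 12% of 25 others (Fisher's exact p = 1), and 62.5% had all probes on 1 side of 0 against 76%. The genes were too few to tell these apart. H2-Aa had probes at 1 and -1.52, and D17H6S56E-5 had probes at -3.80 and -3.70.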

How the results depend on the processing

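The scan campaign block, the fits within 1 scan day or campaign, the fit without campaign 1, and all alternatives of the 20 weeks versus 10 days and single-dye comparisons were chosen after the data were examined. Counts of genes moved by over 1.5 times in the cases given here, and the cause was not tested unless stated. With normexp background correction and loess, fewer genes reached a 2-fold ratio to the reference: 27 over all ages, 68 at 10 days, 88 at 4 weeks, 90 at 8 weeks, 341 at 12 weeks, 198 at 16 weeks and 279 at 20 weeks. Its offset shrinks ratios by construction, and 16 versus 12 weeks gave 402. Of these, 25, 64, 87, 76, 341, 196, 270 and 154 were shared with the counts in the report. The share of higher genes went from 39.5% to 57.4% at 10 days, from 65.8% to 85.2% at 4 weeks, from 24.1% to 12% at 12 weeks and from 35% to 57% at 20 weeks. Keeping only genes well above background in both dyes on all arrays, thus fewer genes, gave 28 over all ages and 92, 76, 167, 603, 398 and 938 at the ages in order, and 536 for 16 versus 12 weeks. With no filter 8 weeks gave 927 and 16 versus 12 weeks 136. Where a dye was not above background the files hold surrogate values, which limits the size of a ratio there. Array weights gave 4007 for 4 weeks versus 10 days and 584 for 16 versus 12 weeks. Fitting only the ages compared gave 3135 for 8 versus 4 weeks and 1 for 16 versus 12 weeks. An adjusted p under 0.01, stricter by construction, gave 343 at 8 weeks, 1077 for 4 weeks versus 10 days, 2428 for 8 versus 4 weeks, 2327 for 12 versus 8 weeks, 5 for 16 versus 12 weeks, and 2041 and 5435 in the NOD and reference dye on scan day 6. The campaign block gave 45 at 4 weeks, 896 at 12 weeks and 164 at 16 weeks, 1 for 4 weeks versus 10 days, 10 for 8 versus 4 weeks, 945 for 12 versus 8 weeks, 11 for 16 versus 12 weeks, 627 for 20 versus 16 weeks, 1062 for 20 versus 4 weeks and 3844 for any change. Under it the share of higher genes went from 65.8% to 35.6% at 4 weeks and from 28.3% to 48.2% at 16 weeks. Its values for 4 weeks rest on the single 10-day array of campaign 1. With fewer arrays, 4 weeks versus 10 days gave 1 and 12 versus 8 weeks 1145 within 1 campaign, and within 1 scan day 20 weeks versus 10 days gave 4842 and 16 versus 12 weeks 0 with limma, with 2182 at an unadjusted p under 0.05. Without campaign 1, 394 genes differed over all ages. The NOD dye alone gave 12828 for 4 weeks versus 10 days, 58 for 12 versus 8 weeks, 1 for 16 versus 12 weeks, 3003 for 20 versus 16 weeks and 5528 for 20 weeks versus 10 days. Quantile scaling of average signals leaves ratios unchanged by construction and tested nothing here.

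Leaving out 1 array gave 170 to 224 genes over all ages, 224 to 535 at 10 days (535 without replicate 4), 611 to 771 at 4 weeks, 445 to 591 at 8 weeks, 1353 to 1889 at 12 weeks, 1491 to 2101 at 16 weeks and 3148 to 3371 at 20 weeks. It gave 1888 to 2621 for 4 weeks versus 10 days, 3090 (without replicate 3 of 8 weeks) to 5238 for 8 versus 4 weeks, 2592 (without replicate 2 of 8 weeks) to 4591 for 12 versus 8 weeks, 7847 to 8712 for 20 versus 16 weeks, 9930 to 10647 for 20 versus 4 weeks, 13857 to 14800 for any change and 7805 to 8698 for 20 weeks versus 10 days. For 16 versus 12 weeks it gave 6 (without replicate 4 of 16 weeks) to 623 (without replicate 1 of 12 weeks), with 339 without replicate 3 of 16 weeks. Without replicates 2, 3, 4 and 5 of 12 weeks that comparison gave 102, 47, 63 and 78, and without replicate 1 of 16 weeks 28. On scan day 6 the NOD dye gave 2418 (without replicate 1 of 10 days) to 4503, with 2900 without replicate 3 of 10 days, and the reference dye 7071 to 9162.

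Among 219 gene values, 127 kept their direction and side of the threshold with the campaign block, 81 no longer passed, 3 newly passed and 8 reversed: Insc at 4 weeks (-1.15), Insc for 8 versus 4 weeks (1.40), and for 20 versus 4 weeks Insc (1.30), Nlrx1 (1.64), Oosp1 (0.19), Spsb1 (0.80), Olfr448 (1.35) and Wdr54 (0.49). The cause was not tested. With the mean of probes 211 of 219 gene values stayed the same, 7 no longer passed, and H2-Aa, whose probes differ in sign, reversed (-0.26). The NOD dye alone leaves out the reference by construction and reversed Dct (-1.11) and Mucl2 (-0.91) for 4 weeks versus 10 days, Reg3b (-0.25), Dmbt1 (-0.79) and Tff2 (-1.26) for 12 versus 8 weeks, Pla2g1b (0.90) and Crem (0.11) for 16 versus 12 weeks, and Dct (-1.51), Anxa1 (-0.21), Camp (-0.26), Ctsg (-0.47) and Olfr1497 (0.01) for 20 weeks versus 10 days. It reversed the lists of neutrophils (-0.89), megakaryocytes (-0.10) and adipose tissue (0.44) for 4 weeks versus 10 days, and of regulatory T cells (0.22) and S phase (-0.14) for 8 versus 4 weeks. For mast cells from 10 days to 4 weeks the direction of the test against other genes turned, while the median (0.14) kept its sign. The exocrine pancreas list reversed for 12 versus 8 weeks (-1.39) and 16 versus 12 weeks (2.33), and for 20 versus 4 weeks natural killer cells (0.37), type I interferon (0.10) and diabetes candidates (0.29) did. For 20 weeks versus 10 days it reversed B cells (0.45), T cells (1.49), regulatory T cells (0.52), natural killer cells (1.41), erythroid cells (-0.27), adipose tissue (0.38), G2 and M phase (-0.85) and type I interferon (0.28). Of 126 list tests 22 held with an estimated correlation, and 77 of 86 held with the campaign block. With fry, which does not compare a list with other genes, 114 of 126 passed.

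Replicate numbers do not pair the arrays: same-numbered arrays of different ages deviated together at a median r of -0.01 across genes (-0.20 to 0.18, 61 pairs), and 6 of 27 arrays were closest to their own number. With the replicate number as a block, 16 versus 12 weeks gave 137 genes, and the other 7 counts stayed within 1.5 times.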

Other observations

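Testing other splits of the arrays was planned, the comparisons of 20 weeks with 10 days and within 1 scan day were added after the data were seen, and the other values here were looked at after the results were seen.

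Olfactory receptor genes made up 775 of the genes tested, and their share that differed was not tested against that of other genes. It was 1.16% at 10 days (other genes 1.04%), 1.03% at 4 weeks (2.55%), 1.55% at 8 weeks (2.32%), 5.94% at 12 weeks (5.85%), 8.52% at 16 weeks (6.19%) and 16.5% at 20 weeks (12.1%). At 20 weeks 94 of 128 were lower and at 16 weeks 54 of 66. It was 15.6% against 35.3% for 20 versus 16 weeks and 14.3% against 34.5% for 20 weeks versus 10 days.

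Of the 133 genes lower in NOD over all ages, 21 followed the exocrine pancreas list across arrays at r above 0.9, 17 of them in that list. At 8 weeks 17 of 504 lower genes did, at 16 weeks 33 of 1166, and 0 at 12 and 20 weeks. Chromosome 6 held 13 of 960 genes that differed over all ages (1.35%, odds ratio 2.56, Fisher's exact test, adjusted p = 0.035). With the 6 ages taken as 6 samples, 152 genes differed over all ages.

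Red-dye profiles of the same age on different scan days correlated across genes at 0.85 to 0.99 (median 0.90, 16 pairs of arrays).

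Other splits of the arrays into groups of the same sizes were tested in the 25236 genes without missing values. Chance could be excluded for 4 weeks versus 10 days (2622 genes, highest other split 700), for 20 versus 4 weeks (10789 and 3178), for 20 weeks versus 10 days (8618 and 2490), for 12 versus 8 weeks (4389 and 1278) and for any change from 4 to 20 weeks (14440 and 1466), each with 1 split as large, the real one. It could also be excluded for 8 versus 4 weeks (4595 and 4423) and for 20 versus 16 weeks (8831 and 6095), where the highest other split nearly exchanged the ages. These splits treat arrays of all scan campaigns as exchangeable, so they cannot tell age from campaign. They are splits of ratios, whose reference could be the same control RNA on arrays of an age. They therefore do not cover variation between control mice. With the campaign block 20 versus 16 weeks gave 627 genes and 20 weeks versus 10 days 6738. For 16 versus 12 weeks 2 of 100 splits gave as many genes (201 for the real one). The higher one, with 614, put replicate 1 of 12 weeks with the 16-week arrays, all of scan day 5, against the other 12-week arrays of scan days 3 and 5, so it follows scan day in part. Within scan day 5 the real count was 0 with limma, which every split reaches, so the 35 splits (highest other 1) could not test chance there. Within scan day 6, chance could be excluded for the NOD dye (4798 genes, 0 in the highest other split). The ratio gave 4828 and the reference dye 8927, also with 0 genes in the highest other split of each. Reference arrays of an age could be repeats of the same control RNA. The counts of the reference dye and of the ratio, which contains it, thus do not tell how control mice vary. A split of the 8- and 12-week arrays that follows campaign 2 gave 2 genes.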
